A study of Arabidopsis thaliana with 12 samples.

How the data were processed

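Total RNA of wild-type Arabidopsis thaliana plants of the Landsberg ecotype was measured in 12 samples, 6 from plants given water and 6 from plants given 50 µM paraquat. Per the labels, all plants had spent 12 h in the dark and were sampled 30 min after their return to light. Paraquat is a bipyridinium herbicide that takes electrons from photosystem I in the light and passes them to oxygen. The labels call it a benzoquinone, which its structure is not. The labels number the samples 1 to 6 in each group and do not say whether the numbers stand for separate plants, separate hybridisations or repeated readings, so p-values measure only the spread between these samples, which may be technical.

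The deposited values are array intensities on a linear scale, 1 per probe and sample. How the authors obtained them (scanner, background correction, scaling) is not given in the sources used here. Column means lay between 0.944 and 1.07, so the values had been scaled before deposit, to a reference that stays unknown. Exact zeros occurred in every column, 108 to 148 of 3439 probes, and 20 probes were at 0 in all 12 samples. Signals seem to be held at a ceiling just under 100, a value shared by several samples, and 3 probes reached it in at least 1 sample; none of those is named here. Arrays give no read depth, so the number of samples limits the precision.

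Column medians lay between 0.443 and 0.491 under water and between 0.563 and 0.635 under paraquat, which differ by more than the limit of 10% set in advance, so the columns were quantile normalized. Zeros were first set to the lowest value above 0 of their column, and log2 was taken after normalization, which puts every zero at -10.36. Setting zeros after normalization instead called all 20 probes that were at 0 throughout as changed, and is given as an alternative only. Fold changes are paraquat minus water on the log2 scale. Each probe was tested with lmFit and eBayes of limma 3.58.1 in R 4.3.3, two-sided, over all 12 samples without a block, with Benjamini-Hochberg adjustment over 3439 probes and a threshold of 0.05. Figures were drawn with matplotlib.

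Probes were named through the platform annotation, with symbols updated by gene identifier from the RefSeq table of assembly TAIR10.1. Of 3439 probes, 692 had 1 gene, 870 had several and 1877 were not listed, so that these are unnamed here. The 692 probes held 691 different genes, and 690 of the probes were matched in RefSeq. No gene is named from a probe with several genes, and no coordinates are given because no array build is named.

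The genes named are the 15 largest rises and the 15 largest falls past the threshold among probes with 1 gene, and per fixed list up to 4 members past the threshold with the smallest p, or the member with the smallest p if none passed. A further part of the rule named 14 stress and photosynthesis genes whatever their values, and none of these had a probe of its own. The 26 lists fixed before the data were examined hold 340 genes, of which 13 on 9 lists had a probe of their own. No fixed list had 3 such genes, and 5 lists defined by description matched no probe because the tables used here carry no descriptions. Another 10 lists were therefore assembled from gene identity after the table was opened, and 3 fixed lists were completed with probes that list only several members of the same list. These 13 lists were tested with camera at a preset correlation of 0.01, with an estimated correlation and fry as alternatives. Genes named outside the rule were chosen after their values were seen.

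The fit was tested on simulated data. With 200 of 3439 probes changed, 18% were recovered at a log2 change of 0.5 and 68.5% at a log2 change of 1, and 5.26% and 5.52% of the calls were false. The simulated values were independent between samples and carried no effect of probe number. The real data have links between samples and such an effect, as given below, so these rates need not hold for them. Samples with equal numbers deviated together: correlations of their deviations from the group means were 0.505, 0.478, 0.469, 0.452, 0.379 and 0.337 for numbers 1 to 6, over 3186 probes, so the numbers pair the samples by the rule set in advance, and the pairing comes from the data and not from the labels. Neighbouring numbers (1 with 2, 3 with 4, 5 with 6) were the best of 15 ways to pair the samples in both groups, with correlations of log2 values of 0.859 to 0.937 under water and 0.920 to 0.949 under paraquat. Other pairs of samples reached 0.866 under water and 0.929 under paraquat, so the ranges overlap. The overlap came from numbers 3 to 6, which correlated at 0.841 or more under water and 0.912 or more under paraquat. Numbers 1 and 2 stood apart from these, with correlations of 0.756 to 0.797 under water and 0.876 to 0.892 under paraquat. Neighbouring numbers may be repeated readings, in which case n is 3 per group. The median SD over probes was 0.184 within neighbouring pairs and 0.309 between pair means under water. Under paraquat it was 0.173 and 0.201. Standard errors and p-values that use n = 6 may therefore be too small.

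Fold changes also followed probe number with a period of 288. Among 37 multiples of 12 tried, it accounted for most of the variance of log2 fold changes limited to 2 either way. A position-centred alternative was therefore added after the data were examined: in each sample the median of each step of 12 probe numbers within the period was subtracted, then the median of each place within a step. On simulated data with such an effect in the water samples and no changed probe, calls went from 1260 before centring to 1 after it. The simulated effect followed the same steps that centring subtracts, so its removal was bound to follow. That run cannot show whether centring suits the real layout or spares real differences. Other alternatives were median centring, the values as deposited, cyclic loess, the replicate number as a block, leaving out the 25% dimmest probes, a pseudocount of 0.118, trended and robust variances, sample weights, leaving out each sample, neighbouring numbers averaged, and an exact permutation test per probe. Added after the data were examined were the averaged values with the pair as a block, with and without position centring, probes above 0 in all samples, zeros set after normalization, and leaving out numbers 1 and 2 of both groups.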

Results

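The data give the intensity of 3439 gene probes in 12 samples of wild-type Arabidopsis plants of the Landsberg ecotype. The plants were returned to light after 12 h of darkness and sampled 30 min later, 6 samples after treatment with water and 6 after 50 µM paraquat, a herbicide that draws electrons from photosystem I. The median deposited intensity was 0.467 ± 0.020 (SD, n = 6) under water and 0.593 ± 0.028 (SD, n = 6) under paraquat. The labels imply 1 comparison, paraquat against water, which asks how transcript levels differed shortly after the return to light in the presence of the herbicide.

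Under paraquat the transcript of PRXIIE (AT3G52960), the plastid type II peroxiredoxin that reduces peroxides, was 5.39-fold higher than under water (log2 2.43 ± 0.21, SE, n = 6 per group; 1.68 after position centring, described below), and that of DHAD (AT3G23940), a dehydratase of branched-chain amino acid synthesis, was 5.81-fold higher (log2 2.54 ± 0.13; 1.89 centred). Cpn60beta4 (AT1G26230), a subunit of the plastid chaperonin, rose 4.26-fold (log2 2.09 ± 0.29; 1.62 centred). Its deposited mean went from 0.123 to 0.505, and the first lies near the 5th percentile of values above 0 (0.118). The size of its rise therefore rests on a dim water signal. The Calvin cycle enzyme phosphoribulokinase (PRK, AT1G32060) fell by 1.24 ± 0.23 on the log2 scale (-1.01 centred), and FTRB (AT2G04700), a subunit of the ferredoxin-thioredoxin reductase that passes electrons from photosystem I to thioredoxins, fell by 1.38 ± 0.18 (-1.07 centred). GLDH (AT3G47930), which catalyses the last step of ascorbate synthesis, fell by 1.49 ± 0.11 (-0.90 centred); it was chosen after its values were seen. Each of these 6 genes moved in the given direction in all 6 numbered pairs of samples.

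Of 3439 probes, 1805 differed between the groups (52.5%), 826 higher and 979 lower under paraquat, and 1627 of them moved the same way in all 6 numbered pairs. At least a 2-fold change was found in 795, 389 higher and 406 lower. Among the 692 probes with 1 gene, 165 were higher and 182 lower. The share of changed probes that were higher was 45.8% (exact binomial interval 43.4% to 48.1%). That interval takes the probes as independent, but they share the same 12 samples, so it does not measure how certain the share is. The share depended on the scaling: 60.1% with the values as deposited (1111 higher, 738 lower), 39.1% with median centring (716 higher, 1115 lower) and 48.6% with cyclic loess (877 higher, 929 lower). The median log2 fold change of all probes was -0.04 after quantile normalization, 0.19 as deposited and -0.16 with median centring, so directions are relative to the bulk of the probes. With neighbouring sample numbers averaged, 1160 probes passed.

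Fold changes followed the probe number with a period of 288. With log2 fold changes limited to 2 either way, that period accounted for 22.2% of their variance, against at most 4.7% for any of the other periods tried. Across the period, step medians of log2 fold change ran from -0.77 to 0.61. The spread of step medians within a sample was 0.409 ± 0.078 (SD, n = 6) under water and 0.209 ± 0.013 (SD, n = 6) under paraquat. An exact permutation test, two-sided, that takes the 12 samples as independent gave p = 0.00216, the smallest it can give. Values after each sample was centred by position are therefore given for many of the genes and lists below, and values with no such mention are without centring. After that centring 736 probes were higher and 882 lower, and 1157 of the 1805 changed probes passed again in the same direction, while 10 passed in the opposite one. With neighbouring numbers also averaged and kept as a block, 413 were higher and 480 lower, and 737 probes passed in all 3 fits in 1 direction, 156 of them with 1 gene.

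**Figure D1:**
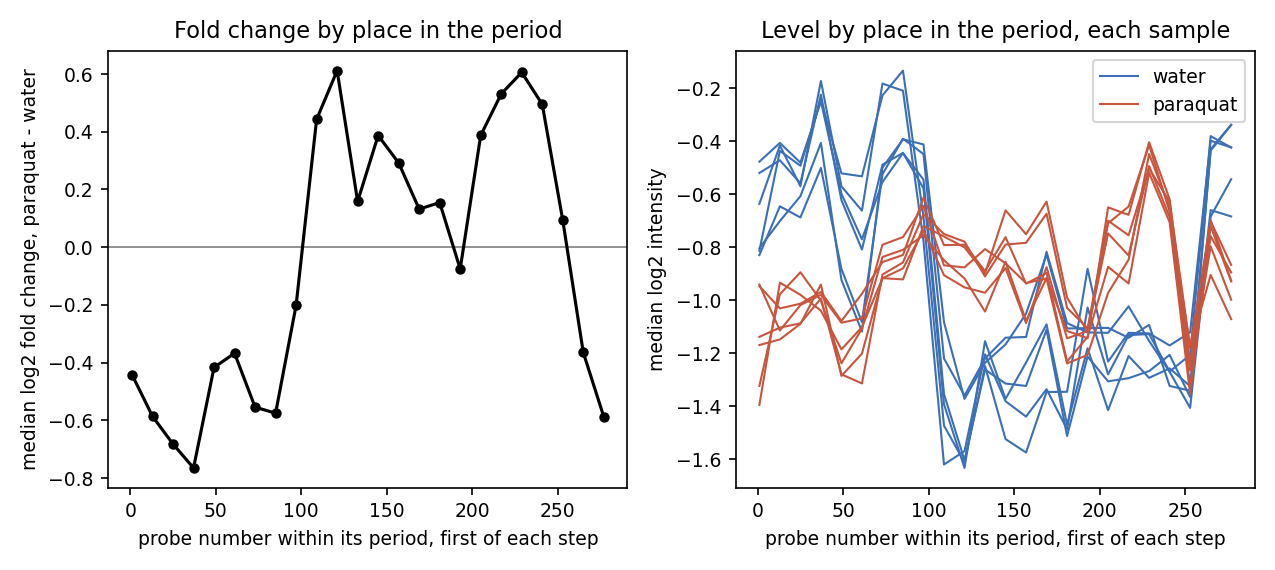
Left, the median log2 fold change (paraquat minus water) of the probes in each step of 12 probe numbers, against the place in the period of 288; right, the median normalized log2 intensity of the same steps in each of the 12 samples. Step medians of log2 fold change run from -0.77 to 0.61, and the lines of the water samples vary more over the period than those of the paraquat samples.

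The largest rise was that of AT4G35660, by 4.19 ± 0.22 on the log2 scale (SE, n = 6 per group, adjusted p = 1.62e-07), from a deposited mean of 0.390 to 7.01. AT3G25680 followed with 3.17 ± 0.17 (SE, adjusted p = 1.86e-07), from a low deposited mean of 0.147 to 1.34. AT5G46390, of a family of carboxy-terminal processing peptidases, rose by 2.79 ± 0.31 (SE). DHAD and PRXIIE came next (adjusted p = 1.46e-07 and 2.56e-06). With neighbouring numbers averaged and their pair kept as a block, the adjusted p was 0.0165 for AT4G35660, AT3G25680, DHAD and PRXIIE alike. AT4G31930 rose by 2.43 ± 0.62 (SE, adjusted p = 0.0063), with the widest error among the 15 largest rises. AT4G09040 rose by 2.41, Cpn60beta4 by 2.09, AT1G32220 by 2.09, AT4G19900 by 2.07, and AT1G01250, of the AP2/ERF transcription factor family, by 2.06. The other 4, AT2G30100, AT5G44000, the F-box gene FBL17 and AT2G28540, rose by 1.91 to 2.04. The deposited water means of AT1G32220, AT5G44000 and FBL17 were low, at 0.168, 0.149 and 0.144, so the sizes of their rises rest on dim signals. After position centring all 15 stayed past the threshold, between 1.16 for AT2G28540 and 3.68 for AT4G35660, with AT5G46390 at 2.16, AT4G09040 at 1.74 and AT1G32220 at 1.34. AT4G31930 lost the call with neighbouring numbers averaged (adjusted p = 0.0821), and AT4G31930, AT1G32220 and AT1G01250 lost it when position centring was joined with averaging of neighbours, their pair kept as a block (adjusted p = 0.0518, 0.0665 and 0.0735).

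The largest falls were those of AT4G02580, a subunit of mitochondrial complex I, and AT1G76450. AT4G02580 was listed at 0 in 3 of 6 paraquat samples and AT1G76450 in 1, so their log2 fold changes of -4.47 ± 1.23 and -3.46 ± 1.18 (SE, n = 6 per group) depend on the value given to zeros; with a pseudocount they were -0.83 and -1.72. Their deposited means went from 0.135 to 0.0158 and from 0.552 to 0.112. AT1G03810 fell by 2.29 ± 0.14 (SE, adjusted p = 3.79e-07), from a deposited mean of 6.15 to 1.26. Its adjusted p was 0.0165 with neighbouring numbers averaged and their pair kept as a block. Next came AT4G22490 (-1.87), AT5G38360 (-1.86), AT4G37230 (-1.73), AT4G05030 (-1.71) and AILP1 (-1.70). Their deposited means under paraquat were 0.0951, 0.0645, 0.118, 0.186 and 0.129. These lie under or not far above the 5th percentile of values above 0 (0.118), so the sizes of these falls rest on dim signals. AT2G06040, LpxA, AT4G26370, AT4G30740, AT4G30680, AT1G15140 and AT2G27680 fell, with log2 fold changes between -1.68 and -1.55. After position centring all 15 stayed past the threshold, between -3.93 for AT4G02580 and -1.10 for AT4G22490, with AILP1 at -2.16 and AT1G03810 at -1.74. AT1G76450 lost the call with cyclic loess (adjusted p = 0.0636). With neighbouring numbers averaged AT4G02580, AT1G76450 and AT2G27680 lost it (adjusted p = 0.0542, 0.051 and 0.0985), and AT4G02580, AT4G37230 and AT2G27680 lost it when position centring was joined with averaging and the pair block (adjusted p = 0.0528, 0.0569 and 0.0678).

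**Figure D2:**
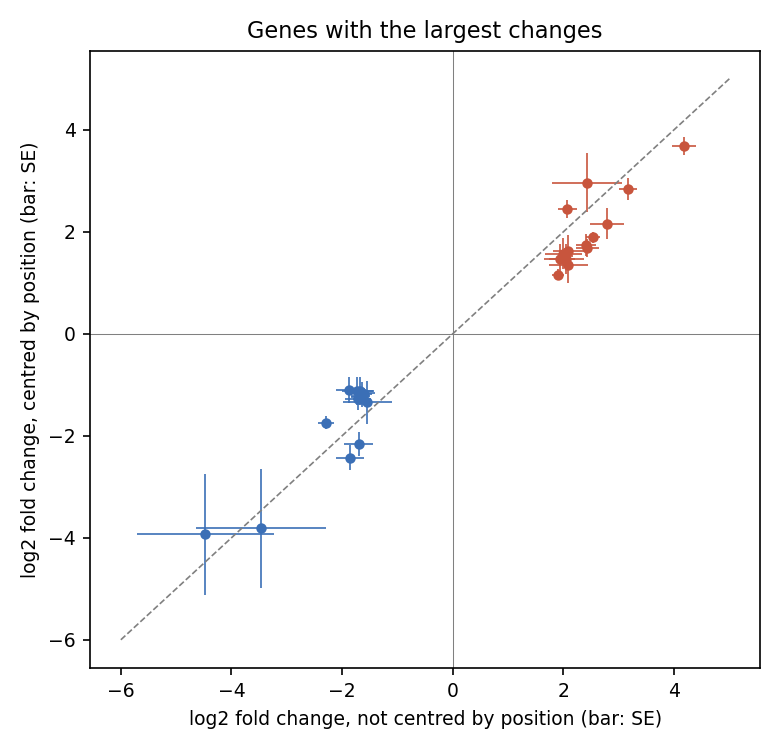
Log2 fold change (paraquat minus water) after position centring against that without it, for the 15 largest rises (red) and the 15 largest falls (blue), with SE bars; the dashed line marks equal values. All 30 points keep their sign, from AT4G02580 at -4.47 and -3.93 to AT4G35660 at 4.19 and 3.68.

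Of the 13 genes of the fixed lists with a probe of their own, 2 rose, 5 fell and 6 did not pass; adjusted over the list alone, 8 passed. The balance turned after position centring, with 6 higher and 2 lower (3 and 2 with averaging and the pair block added), and was 1 higher and 7 lower with median centring, 2 and 3 as deposited, and 1 and 3 with neighbouring numbers averaged. In the photosystems, PSBW of photosystem II rose by 0.34 ± 0.09 (SE, adjusted p = 0.00721), and it was at -0.26 (adjusted p = 0.156) with median centring, 0.09 (adjusted p = 0.6) as deposited and 0.84 after position centring. PSBY of photosystem II fell by 0.38 (adjusted p = 0.0203), did not pass as deposited (adjusted p = 0.248), and was at 0.17 (adjusted p = 0.481) after position centring. PSAN of photosystem I was at -0.06 (adjusted p = 0.828), at -0.63 (adjusted p = 0.034) with median centring and at 0.50 after position centring (adjusted p = 0.0188; 0.102 with averaging and the pair block added). With neighbouring numbers averaged PSBW, PSBY and NTRC did not pass (adjusted p = 0.123, 0.148 and 0.123). The antenna gene LHB1B2 fell by 0.66 ± 0.13 (SE, adjusted p = 0.00141), and was at -0.16 (adjusted p = 0.564) after position centring. In the Calvin cycle, PRK fell by 1.24 ± 0.23 (SE, adjusted p = 0.000675) and was at -1.01 after position centring (adjusted p = 0.00269). SBPASE, the sedoheptulose bisphosphatase of that cycle, was at 0.29 (adjusted p = 0.195) and at 0.74 after position centring (adjusted p = 0.00386; 0.0422 with averaging and the pair block added); it is named outside the rule.

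Among the thioredoxin genes, FTRB fell by 1.38 ± 0.18 (SE, adjusted p = 5.11e-05; -1.07 after position centring, adjusted p = 9.92e-05). NTRC, the plastid NADPH-thioredoxin reductase, fell by 0.47 ± 0.15 (SE, adjusted p = 0.0181) but not with the replicate number as a block (adjusted p = 0.0645), as deposited (adjusted p = 0.522) or after position centring (-0.06, adjusted p = 0.781). PRXIIE was the antioxidant gene of the fixed list with a probe of its own. The list members CHLM of chlorophyll synthesis (-0.20), APS4 of sulfate assimilation (-0.24) and FATB of fatty acid synthesis (-0.55) did not pass (adjusted p = 0.217, 0.307 and 0.0663). CHLM was at 0.35 after position centring (adjusted p = 0.0284; 0.213 with averaging and the pair block added), and FATB passed with median centring (-0.90, adjusted p = 0.0145), without water replicate 2 (adjusted p = 0.0372) or without water replicate 4 (adjusted p = 0.0497).

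**Figure D3:**
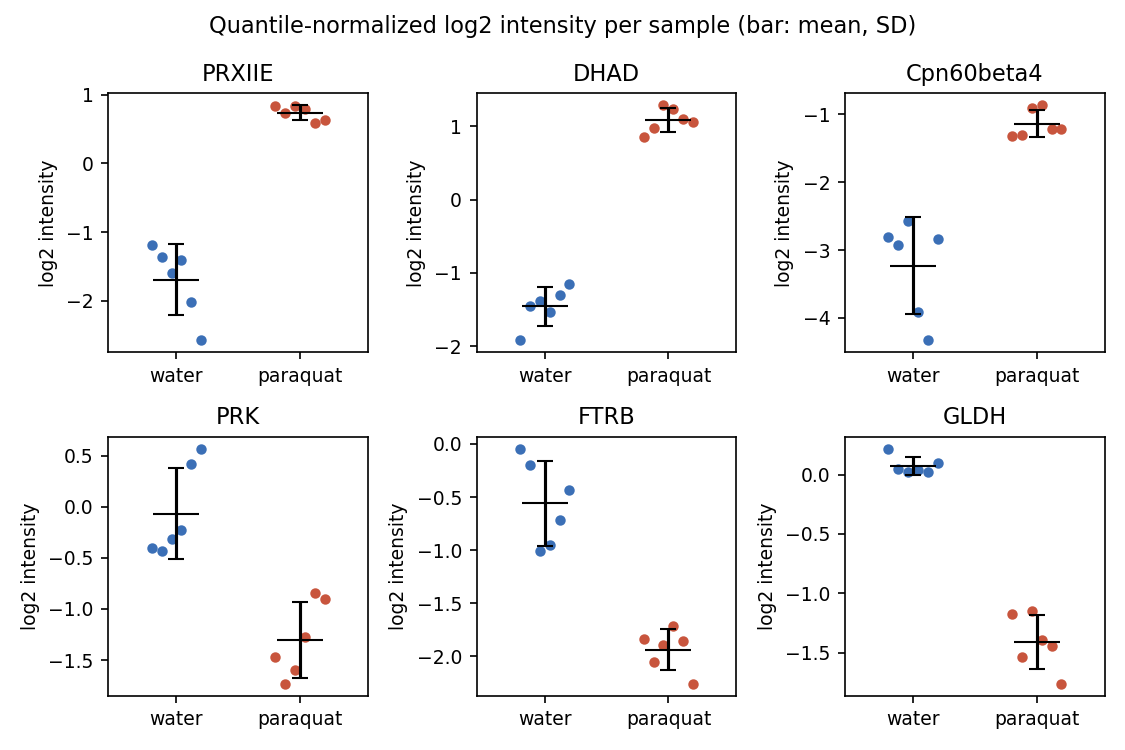
Quantile-normalized log2 intensity of 6 genes in each of the 6 water and 6 paraquat samples (points), with mean and SD (bars); the vertical scale differs between panels. PRXIIE, DHAD and Cpn60beta4 are higher in every paraquat sample than in any water sample, and PRK, FTRB and GLDH are lower.

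Of the 13 lists tested, none passed camera with the preset correlation (lowest adjusted p = 0.371) or with an estimated correlation (lowest adjusted p = 0.45). By contrast fry, which asks whether a list moves on balance 1 way, called 12. It does not set a list against the other probes, and 52.5% of all probes changed, so its calls single out no list. It called amino acid synthesis higher (fry, adjusted p = 1.29e-05), though the median log2 fold change was -0.36 and only DHAD rose. The antioxidant enzymes, completed with probes that list several of them, had 3 of 4 probes higher under each scaling and 1 of 4 with neighbouring numbers averaged. With averaging and the pair as a block 3 of 4 were higher, with and without position centring. After position centring all 4 were higher, with a median log2 fold change of 0.91 (camera, adjusted p = 0.0417; adjusted p = 0.289 with an estimated correlation). The thioredoxin list, completed likewise, had 2 of 3 lower, and 1 of 3 as deposited, with the replicate number as a block, with neighbouring numbers averaged and after position centring. The tetrapyrrole list had 0 of 3 changed (median log2 fold change -0.20), but 2 of 3 higher after position centring (median 0.35) and 0 of 3 with averaging and the pair block added.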

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

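The correlation over probes that list the same genes was chosen as a test of an effect of place after its value was seen; the comparison of dim with other probes was rerun over all probes, those with zeros included, after a first result was seen, and the splits of averaged columns and the random pairs of probes were added after the data were examined. The check that paired probes agree and the comparison of steps over the periods were not among the tests fixed in advance. The splits of the 12 samples, the drop after centring, the correlation as a test of gene order and the scaling without the brightest probes were fixed before their results were seen.

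The count of 1805 changed probes was set against other groupings of the 12 samples. Of 100 splits into 6 and 6, which held all 32 that part the 6 numbered pairs and 68 drawn from the others, only the real one, 1 of 100, gave as many; the highest of the others gave 0. That share is under 0.05 if the 12 samples are independent, and it says nothing of a technical difference between the groups. If neighbouring numbers are repeated readings, 10 splits of the 6 averaged columns remain, whose share cannot go below 0.1; the real one gave 1160 probes and was the 1 split with as many, and the highest other gave 0.

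Fold changes followed the probe number with a period of 288. In 16 of 16 periods steps 0 to 7 had a lower median log2 fold change than steps 9 to 20. These steps follow the low and high stretches of the profile of the same fold changes. The direction over all periods together was therefore bound to follow. Its return in each single period was not, and that argues against genes sorted by function only once along the probe numbers. An effect of the place on the filter and an order of genes by function that repeats in each period cannot be told apart here. Probes that list the same genes were to decide between them, since gene order predicts no link with place within such a pair. Over 82 pairs the difference in log2 fold change did correlate with the difference in the position profile of all other probes (Pearson's r 0.416, permutation p = 0.00019). By the rule set in advance this correlation counted against gene order. It decides nothing here, because paired probes did not clearly agree better than random ones. Their median absolute difference was 0.820 over the 82 pairs and 0.849 over 80 sets with 1 pair each, against 0.843 over random pairs. Log2 fold changes within the 80 sets correlated with a rho of 0.126 (permutation test, one-sided, p = 0.132). Random pairs also gave a median r with the position profile of 0.504 (95% of draws 0.322 to 0.649). Centring by position lowered the median absolute difference within pairs by 0.0974 (bootstrap interval -0.111 to 0.383), and over random pairs by 0.130. Most of these probes list several genes, so the members of a pair may measure different relatives. If genes were ordered by function, centring would also remove real differences. A response to paraquat that depends on the place has no counterpart in the design, and no biological explanation was tested.

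The deposited medians were higher under paraquat in all 6 numbered pairs, by 0.344 on the log2 scale. An exact permutation test, two-sided, that takes the 12 samples as independent gave p = 0.00216, the smallest it can give. Scaling each column without its 35 brightest probes left 0.195, still higher in all 6 pairs, which argues against bright probes as the whole cause. A higher background left in the values under paraquat should raise dim probes most, but the median log2 ratio of the dim probes (lowest of 3 equal classes) was 0.0102 against 0.287 in the middle class, a difference of -0.277 (bootstrap interval -0.373 to -0.181). Whether background was subtracted before deposit is unknown. After subtraction a higher background need not raise dim probes, so the test cannot exclude that case. A general rise of transcripts under paraquat and the authors' unknown scaling stay open, untested.

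In 6 of 86 groups of 6 samples 1 sample lay far from the others by Dixon's ratio of gap to range at the 95% level; chance gives about 4.3. The values were 0.638 for LHB1B2 in water sample 6, 0.652 for the number of zeros in water sample 2 (108, next 123), 0.83 for AT5G46390 in paraquat sample 2, 0.674 for AT4G31930 in paraquat sample 4, 0.83 for AT1G76450 in paraquat sample 1, which is listed at 0, and 0.717 for FATB in paraquat sample 1.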

How the results depend on the processing

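Position centring, the averaged values with the pair as a block, their combination, and the settings on zeros and on numbers 1 and 2 were chosen after seeing the data. The cause of the changes was not tested, except that averaging leaves fewer columns. Leaving out 1 sample at a time gave 1681 to 1813 changed probes, 752 to 817 higher, 929 to 996 lower, 44.2% to 46.3% higher, 7 to 8 list members and 0 lists. With the replicate number as a block, which the pairing supports, 1964 probes changed (913 higher, 1051 lower); among the genes named by the rule it ended the call of NTRC and changed no other call. The share that were higher was 39.1% with median centring, 60.1% as deposited, 48.6% with cyclic loess, 48.3% without the 25% dimmest probes and 42.4% with neighbouring numbers averaged. Averaging gave 1160 changed probes, 492 higher, and 4 list members adjusted over the list alone, against 8; with the pair block 541 were higher and 4 list members passed. Position centring with averaging and the pair block gave 893 changed, 413 higher and 480 lower. Leaving out numbers 1 and 2 of both groups gave 1697 changed, 758 higher and 939 lower, and 1496 of the 1805 changed probes passed again in the same direction. Position centring called 1 list, the antioxidant enzymes, which did not pass with an estimated correlation (adjusted p = 0.289), and fry called 12, against 0. Under position centring 11 of the 20 probes at 0 in all samples were called, which shows that centring adds calls among zeros.

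Of the 30 genes with the largest changes, 30 kept direction and threshold with median centring, as deposited, with the replicate block, with the pseudocount and after position centring, 29 with cyclic loess, 26 averaged and 24 with position centring, averaging and the pair block. Where the value passed the threshold before or after the change of setting, the sign turned for PSBW with median centring (-0.258) and, after position centring, for PSAN (0.499), PSBY (0.167, also 0.167 averaged with the pair block), CHLM (0.349), AT1G74470 (0.459), AT3G58610 (0.333) and Cpn60beta3 (-0.376). A further 55 turns of sign, in 19 genes over all settings, had neither value past the threshold, such as APS4, NdhN and PSB27 after position centring (0.413, -0.389 and 0.454), CHLM as deposited (0.117) and PSAN with cyclic loess (0.0653). Averaging 1 with 4, 2 with 5 and 3 with 6 was not run, because the columns did not show those to agree best. The signal over background is unknown, which limits what low values can show.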

Other observations

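The groups described here were assembled after the table was opened, and none passed camera. Of 16 genes for pentatricopeptide repeat proteins, which bind organelle RNA, 5 rose and 2 fell (camera, adjusted p = 0.371). With the replicate number as a block 6 rose and 3 fell, after position centring 4 rose and 1 fell, and with neighbouring numbers averaged 2 rose and 1 fell. The rises depended on scaling, with 3 rising and 2 falling under median centring and 7 and 2 as deposited. AT3G22150 rose by 1.79 ± 0.23 (SE, n = 6 per group; 1.33 after position centring) and AT4G14050 fell by 1.34 ± 0.17 (-0.92 centred). AT5G39980 rose by 1.51 ± 0.28, but lost the call with averaging and the pair block (adjusted p = 0.0657; 0.13 with position centring added). Of 5 genes listed for chlororespiration and the thylakoid NDH complex, which moves electrons around photosystem I, 3 rose and 0 fell (adjusted p = 0.371): CRR41 by 1.60 ± 0.15, NdhS by 1.14 ± 0.33 and CRR21 by 0.70 ± 0.25. CRR21 is also 1 of the 16 pentatricopeptide repeat genes, so it is counted among the rises of both lists. PIFI, listed at 0 in 1 paraquat sample, was at -1.21 and did not pass (adjusted p = 0.446). After position centring CRR41 was at 1.51 and NdhS at 1.59. With the replicate number as a block NdhN also passed (0.21, adjusted p = 0.0319), while its value was -0.39 after position centring. With averaging and the pair block 1 of 5 passed, and NdhS, CRR21 and NdhN did not (adjusted p = 0.0698, 0.118 and 0.234). With median centring 1 of the 5 passed, CRR41. CRR21 was at 0.42 after position centring (adjusted p = 0.161) and missed the threshold without any 1 of 6 samples (water replicates 2, 5 and 6, paraquat replicates 3, 4 and 6; adjusted p = 0.0513 to 0.0667). Of 8 redox and detoxification genes 1 rose (PRXIIE) and 5 fell (adjusted p = 0.371), among them GLDH (-1.49 ± 0.11) and the plastid lipocalin CHL (-1.11 ± 0.22; -1.10 centred). The 5 falls also include FTRB and NTRC, which like PRXIIE are fixed-list genes already given in the Results. With the replicate number as a block 4 fell, and 3 fell as deposited, with neighbouring numbers averaged and after position centring. SRX, sulfiredoxin, fell by 0.44 but was at -0.10 after position centring (adjusted p = 0.691) and lost the call as deposited and with averaging and the pair block (adjusted p = 0.0698).

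Of 6 genes for plastid ribosomal proteins, AT4G01310 rose by 1.06 ± 0.15, and AT1G64510, AT3G13120 and AT3G54210 fell (-0.84, -0.96 and -0.90; adjusted p = 0.663 for the list). After position centring they were at -1.63, -1.39 and -0.52. AT3G13120 did not pass as deposited (adjusted p = 0.0847) or with cyclic loess (adjusted p = 0.0526), which left 2 lower, AT1G64510 lost the call with averaging and the pair block (adjusted p = 0.051), and AT3G54210 lost it with position centring added (adjusted p = 0.0724). AT5G65220, which did not pass, is listed at 0 in 5 of 6 samples of each group. Of 4 endoglucanase genes of family 9B, GH9B8, GH9B11 and GH9B16 fell (-1.21, -0.98 and -0.90; adjusted p = 0.371 for the list), also under each other scaling. After position centring they were at -0.71, -0.47 and -0.59, and they did not pass with averaging and the pair block added (adjusted p = 0.0568, 0.0915 and 0.0583). Of 6 photosynthesis genes 1 rose and 3 fell (adjusted p = 0.663), and 3 rose and 1 fell after position centring (2 and 1 with averaging and the pair block added), 0 and 4 with median centring, and 0 and 2 with neighbouring numbers averaged. These 6 are PSAN, PSBW, PSBY, LHB1B2, PRK and SBPASE, whose values are given in the Results, so they are not further evidence. Of 5 assembly factors of photosynthetic complexes AT1G22700 rose by 0.93 and LPA19 fell by 1.14 (adjusted p = 0.954 for the list). With the replicate number as a block CCB3, which is listed at 0 in 7 of 12 samples, also passed (adjusted p = 0.0495), but not with averaging and the pair block (adjusted p = 0.116). After position centring 1 rose and 2 fell, with AT1G22700 at 1.46 and LPA19 at -0.36, and LPA19 lost the call with averaging and the pair block added (adjusted p = 0.148). Of 4 amino acid synthesis genes 1 rose, DHAD, and 2 rose after position centring (1 with averaging and the pair block added). AT3G58610 and CBL fell with the replicate number as a block (adjusted p = 0.0452 and 0.0315) but not with averaging and the pair block (adjusted p = 0.24 and 0.127). CBL is listed at 0 in 2 of 6 paraquat samples, so its fold change depends on the value given to zeros. Of 3 folding genes Cpn60beta4 rose and AT5G55220 fell by 1.49, and after position centring 2 fell (1 with averaging and the pair block added). AT5G55220 missed the threshold with cyclic loess (adjusted p = 0.0648), without water replicate 1 (adjusted p = 0.0513) and without water replicate 2 (adjusted p = 0.0555). Of 3 histone H3 genes, whose sequences are nearly identical and may share signal, 1 fell, AT1G09200 (-0.83; -1.24 after position centring, where 2 fell, and 1 with averaging and the pair block added). It lost the call with averaging and the pair block (adjusted p = 0.0641). AT5G65360, which did not pass, is listed at 0 in 4 of 6 samples of each group. The adjusted p of the list was 0.663 for amino acid synthesis, folding and histone genes alike.

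Over 80 sets of genes that 2 probes each list, log2 fold changes of the paired probes correlated with a rho of 0.126 (permutation test, one-sided, p = 0.132; 0.029 after position centring, p = 0.399) and their mean levels with a rho of 0.241 (p = 0.0155). Their median absolute difference in log2 fold change was 0.849, against 0.843 over random pairs. In 23 sets both probes passed the threshold, 13 in the same direction and 10 in opposite ones. Only 1 of the 80 sets is a single gene, so the paired probes do not measure the same gene for certain.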
